A study of Hipposideros armiger with 2 samples.

How the data were processed

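RNA was measured by sequencing of poly(A)-selected libraries from 2 great Himalayan leaf-nosed bats (Hipposideros armiger), both labelled as liver from the CW cave and as exposed to heavy metals. They form 1 group, with replicate numbers taken from the sample titles. Samples of the other cave were not analysed here, so no comparison between caves was made, and no p-value between animals was computed for 1 library against 1 library. The study's design text describes separate animals, and the 2 libraries are treated as 2 animals on that basis.

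The authors deposited 1 table per library with the same 55378 assembled genes in both, identified by Trinity cluster names, so the counted features are a de novo assembly. The submitters' processing notes name cutadapt 1.9 for both libraries, and the mm10 mouse build for replicate 1 only; how a mouse build was used with an assembly is not given in the sources used here, nor are the assembler's version and the quantifier. The deposited expected counts, marked as counts per the file headers, are estimates with decimals and were rounded to whole numbers before scaling. The second column of values deposited by the authors was read as TPM, since it summed to 996837 and 996239 over the 55378 genes. Its header gives no unit, and how it was computed is not given in the sources used here. A gene name in the text is the best Swiss-Prot protein match that the authors' tables list. Such a match does not show which species a transcript came from, and 1 name can cover several assembled genes, between which reads of near-identical copies can be split. Of the 12783 distinct names, 10976 were symbols in the RefSeq gene table of the bat assembly ASM189008v1, from which no coordinates were used. The tables' second description column was filled for 10430 assembled genes and named mostly plants and algae, led by Quercus suber with 1058, and was not used for names.

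The libraries held 18741210 and 18778331 expected counts, and 51177 and 47711 assembled genes had a count above 0. A count of 3, taken as the detection floor, corresponded to about 0.082 TPM in replicate 1 and 0.09 TPM in replicate 2 for a transcript of typical length. Wilson 95% intervals are given for shares of counts; they and the floor cover counting error only, since reads without molecular identifiers are not independent molecules.

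Levels of 31 gene lists, fixed before the data were examined, were given as TPM summed over all assembled genes with a member's name, with the mean and SD over both libraries. Agreement was measured across genes with at least 1 TPM in either library on the log2(TPM + 1) scale. For differences between the libraries, TMM factors from edgeR 4.0.16 (R 4.3.3) were 0.9096 and 1.0993. Log2 ratios of replicate 2 over replicate 1 were taken on log2(CPM + 1) among genes with a mean of at least 1 CPM, and their median was removed; this pseudocount understates changes of low genes. For each list with at least 5 tested members, the median ratio was placed among 10000 random lists of the same size, matched on mean expression in 20 bins with seed 1. These percentiles describe 2 libraries and are not p-values. The computations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

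The rule for named genes, fixed before the data were examined, took the 15 assembled genes with the highest mean TPM, up to 4 highest members of each list, and the 8 higher and 8 lower genes with the largest ratios among named genes with a mean of at least 10 CPM. Other genes named were chosen after their values were seen. Some genes that the rule takes are not reported here. The procedure was tested on simulated counts for the ratio of replicate 2 over replicate 1, with 21582 genes passing the filter. It called 100% of 50 genes at each simulated change of 4-fold and 16-fold in either direction, and 0.0% of unchanged genes. The changed genes were drawn above a higher expression floor than the filter of 1 CPM, and a single fixed spread was simulated. How many changes are found near that filter was therefore not measured. Of 100 unchanged simulated lists, 6 lay outside the 2.5 to 97.5 percentiles.

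Alternatives chosen before the data were examined were a pseudocount of 0.1, other filters on low values, library size scaling, DESeq2 1.42.0 size factors (0.9143 and 1.0937), leaving out each replicate, and leaving out the 10 highest genes. A set of genes over 16-fold lower in replicate 2, 8 further lists of tissue markers, and the alternatives that use them were added after the data were seen. That set was first defined on unscaled counts and then redefined on TMM-scaled counts. It takes assembled genes with at least 100 summed counts whose log2 ratio of counts + 1, TMM-scaled and less its median, is below -4, as in the mitochondrial results; by the ratio of CPM + 1 used for the lists, 170 genes were over 16-fold lower and 0 over 16-fold higher. The 3 planned results on the authors' own comparison of the caves were not run, because the tables used here have no comparison columns.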

Results

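The data are gene expression values from libraries labelled liver of 2 great Himalayan leaf-nosed bats caught in the CW cave, with 18741210 expected counts in replicate 1 and 18778331 in replicate 2. The study addressed liver function under heavy metal exposure. With 1 group, the design allows a description of the transcripts in these libraries and of how far the 2 libraries differed.

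The first question was which transcripts the CW libraries held. On the fixed list of mitochondrially encoded respiratory chain genes, the members found took 23.2% of TPM in replicate 1 and 15.2% in replicate 2. That list does not hold the names MT-ND3 and MT-ND6. Among the other gene lists, erythroid genes summed highest, with the oxygen-carrying globins HBA at 19523 ± 2556 TPM and HBB at 13526 ± 1991 TPM (mean ± SD, n = 2 here and below). Cytosolic ribosomal proteins summed to 18206 ± 2700 TPM, with RPLP1 at 1146 ± 167 and RPS18 at 1136 ± 198. Hepatocyte secreted proteins differed most: they summed to 16348 TPM in replicate 1 and 441.0 TPM in replicate 2. ALB, the main plasma protein made by hepatocytes, was at 7990 and 176 TPM.

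Surfactant and airway epithelium genes, a list added after the data were seen, summed to 13094 TPM in replicate 1 and 20837 TPM in replicate 2. SCGB3A1, a secretoglobin of airway epithelium, was at 10484 ± 3414 TPM and was among the 15 highest assembled genes. SFTPC, the surfactant protein of alveolar type II cells, was at 3300 ± 1056 TPM, and SFTPB at 588 ± 178. Of 22 members found, 18 reached 10 TPM in replicate 1 and 20 in replicate 2. Their sum was 0.8 times that of hepatocyte secreted proteins in replicate 1 and 47.2 times in replicate 2. The order in replicate 1 rests on 1 ALB assembled gene of length 293, with 6180 TPM from 11784 counts. That is more than the gap between the 2 sums. The surfactant and airway sum in turn came mostly from 1 Scgb3a1 assembled gene, at 8069 and 12898 TPM. The ratios of 0.8 and 47.2 therefore depend on single assembled genes on both sides.

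The 15 highest assembled genes also included those with the protein names Tes (42212 ± 3851 TPM) and Nlrc3 (41662 ± 3922 TPM). Together these held 17.48% and 17.7% of all counts. A best protein match does not show that they are mRNAs of these proteins, and this was not tested. ART2 (27066 ± 1885 TPM) and TAR1-A (18955 ± 1652 TPM) matched yeast proteins; the yeast TAR1 gene lies antisense to ribosomal RNA. Assembled genes with the names TAR1, ART2 or ART3 held 7.24% and 7.13% of counts. The others were MT-ATP6, MT-ND2, MT-CO2, MT-ND5, 2 assembled genes each of MT-CO1 and MT-CO3, HBA, HBB and Scgb3a1.

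Metal handling genes were measured in both libraries. Of the metallothionein and zinc transport list, 17 of 24 members were found; no assembled gene had the name of MT1 or MT2. A metal-binding metallothionein with the name MT4 was at 1156 TPM in replicate 1 and 333 TPM in replicate 2, while the zinc transporters SLC39A7 and SLC39A1 were at 35.0 ± 7.0 and 28.0 ± 2.9 TPM. Iron and copper handling genes summed to 7305 ± 202 TPM, led by HP, which binds free hemoglobin, at 5160 and 6997 TPM. The heme carrier HPX was at 1392 and 44.2 TPM, and HAMP, the hormone that limits iron uptake, at 132 and 10.6 TPM.

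Among genes of oxidative defence, SOD1 was at 502 ± 7.6 TPM, PRDX1 at 484 ± 14.8 and GPX1 at 428 ± 3.9, whereas GPX3, a secreted glutathione peroxidase, was at 536 and 156 TPM. CAT, which breaks down hydrogen peroxide and is named after its values were seen, was at 403 and 57.0 TPM. Glutathione and NRF2 targets summed to 866 ± 38.6 TPM, with the epoxide hydrolase EPHX1 at 210 ± 24.4. Heat shock and ER stress genes summed to 3216 ± 94.7 TPM, led by HSP90AA1 at 703 ± 76.5 and HSP90AB1 at 562 ± 55.8. Apoptosis and p53 target genes summed to 695 ± 44.8 TPM, with MCL1 at 167 ± 21.8. Interferon response genes summed to 490 ± 106 TPM, led by ISG15 at 180 ± 60.4, and innate immunity and inflammation genes to 565 ± 90.8, led by NFKBIA at 138 ± 21.1.

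Markers of other cell types were present. Neutrophil markers summed to 1726 ± 474 TPM, with S100A8 at 685 ± 185. Cholangiocyte markers, which include keratins shared by many epithelia, summed to 972 ± 262 TPM, with KRT19 at 354 ± 108. Stellate cell and extracellular matrix genes summed to 1720 ± 243 TPM, endothelial genes to 852 ± 151, Kupffer cell and macrophage genes to 729 ± 121, and lymphocyte genes to 156 ± 22.97. The stellate and Kupffer cell sums were led by TAGLN (423 TPM) and LYZ (303 TPM), which are not particular to liver. They do not show that liver stellate or Kupffer cells were present. Cell cycle genes summed to 173 ± 43.9 TPM, circadian clock genes to 254 ± 47.8 and cholesterol synthesis genes to 392 ± 52.1. Pancreas and gut genes summed to 10.2 TPM in replicate 1 and 3.45 TPM in replicate 2.

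**Figure D1:**
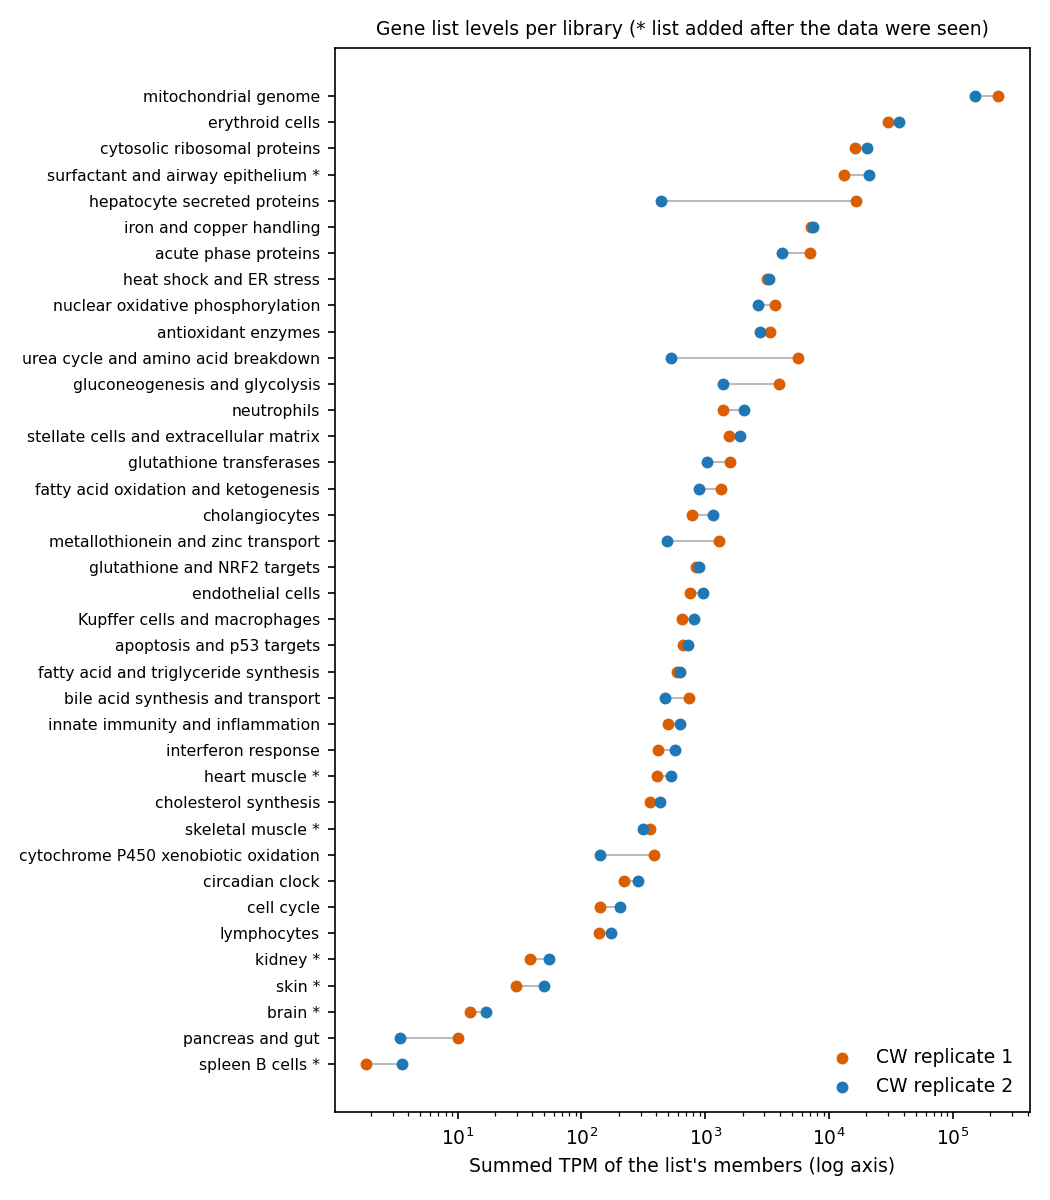
Summed TPM of each gene list (log axis) in CW replicate 1 (orange) and replicate 2 (blue), 1 point per library; an asterisk marks lists added after the data were seen. Hepatocyte secreted proteins are at 16348 and 441.0 TPM, while cytosolic ribosomal proteins are at 16297 and 20115 TPM.

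The second question was how far the 2 libraries differed. Hepatocyte secreted proteins, urea cycle and amino acid breakdown genes, and most acute phase proteins were lower in replicate 2 by large factors; HP, a plasma protein of the iron list, was not, with a log2 ratio of 0.04. In contrast, the medians of the fixed lists of other cell types, stress and immunity lay close to that of all genes. All 20 hepatocyte secreted proteins were over 2-fold lower in replicate 2, with a median log2 ratio of -4.95: APOE was at 2987 and 72.0 TPM, KNG1 at 1172 and 25.4 TPM, and APOC3 at 1091 and 44.6 TPM. Of 27 urea cycle and amino acid breakdown genes, 23 were over 2-fold lower, with a median of -4.22. The urea cycle enzyme ASS1 was at 1003 and 33.1 TPM, and HPD of tyrosine breakdown at 748 and 61.4 TPM. Both lists lay at percentile 0.0 of random lists.

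Acute phase proteins had a median log2 ratio of -3.88, with 15 of 20 over 2-fold lower in replicate 2. ORM1 was at 1107 and 24.2 TPM and ITIH4 at 871 and 39.5, whereas LCN2, which binds bacterial siderophores, was at 2019 and 3158. Cytochrome P450 genes of xenobiotic oxidation had a median of -1.90, with 6 of 10 tested members over 2-fold lower. The median was -1.02 without a filter on low values. It was -0.64 without the genes over 16-fold lower in replicate 2, a set chosen for low ratios. CYP2E1 had a log2 ratio of -4.13 (3887 and 247 counts, but 118 and 58.3 TPM summed over 5 assembled genes of unequal length), and CYP2C19 one of -2.94. Bile acid genes had a median of -1.51, with 14 of 19 over 2-fold lower, while the bile acid importer SLC10A1 had a log2 ratio of -0.37 on counts (1297 and 1196) although its summed TPM were 229 and 298. Gluconeogenesis and glycolysis genes had a median of -1.11, with PCK1, which commits carbon to glucose synthesis, at 772 and 30.6 TPM.

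Smaller median log2 ratios were those of glutathione transferases (-0.75), fatty acid oxidation and ketogenesis (-0.72), nuclear oxidative phosphorylation (-0.71) and the mitochondrial genome (-0.60). Iron and copper handling (-0.31), antioxidant enzymes (-0.29), and fatty acid and triglyceride synthesis (-0.15) also lay below the 2.5 percentile. Without the genes over 16-fold lower in replicate 2, iron and copper handling (-0.08) and the mitochondrial genome (-0.06) moved inside the limits. Those genes were chosen for low ratios, so leaving them out raises such medians by construction. Under library size scaling, which leaves the median of all genes at 0.23, fatty acid and triglyceride synthesis had a median of 0.09 and stayed below the lower limit. In total 13 of the 30 tested lists fixed before the data were seen lay below the 2.5 percentile and 0 beyond the matching upper limit. Of the lists added later, surfactant and airway epithelium lay above it, with a median of 0.21 and 19 tested members, and skeletal muscle (-0.62) lay below the lower one. Among the fixed lists between these limits, cholangiocyte markers had a median of 0.16 (percentile 97.0), neutrophil markers 0.16, interferon response 0.06, heat shock and ER stress -0.04, and erythroid genes -0.06.

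The remaining lists between the limits had medians of -0.14 for metallothionein and zinc transport, -0.04 for glutathione and NRF2 targets, 0.01 for cholesterol synthesis and 0.04 for innate immunity and inflammation. Apoptosis and p53 targets had -0.02, cell cycle 0.04, circadian clock 0.06, Kupffer cells and macrophages -0.14, stellate cells and extracellular matrix 0.05, endothelial cells 0.10, lymphocytes -0.03 and cytosolic ribosomal proteins -0.06. Single members of lists between the limits were over 2-fold lower in replicate 2, and 0 were over 2-fold higher. They included 3 of 12 endothelial and 2 of 13 Kupffer cell and macrophage genes: CLEC4G (-3.02), STAB1 (-1.89) and STAB2 (-1.20), which mark liver sinusoidal endothelium, and MARCO (-3.43) and CD5L (-1.67) of macrophages. They also included 4 of 24 glutathione and NRF2 targets (OSGIN1, -2.23; HMOX1, -2.15; ABCC2, -1.91; GGT1, -1.01) and 2 of 14 metallothionein and zinc transport genes (MT4, -1.94; SLC39A5, -1.81). Further ones were CD8A (-2.73) of lymphocytes, RGS5 (-1.90) of stellate cells and HSPA1B (-1.53) of heat shock. Apart from MT4 and CD8A, these genes were named after their values were seen. Without a filter on low values, metallothionein and zinc transport (-0.17) and Kupffer cells and macrophages (-0.15) fell below the lower limit. Pancreas and gut genes had 2 tested members and no percentile.

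Of 22025 assembled genes tested, 1499 were over 2-fold lower in replicate 2 and 22 over 2-fold higher; those higher were 183 with a pseudocount of 0.1, 57 with library size scaling, 36 without a filter on low values and 4 at a mean of at least 10 CPM. Among named genes with a mean of at least 10 CPM, the 8 lowest were 2 of MT-CO1, 2 of MT-ND3, and 1 each of MT-CYB, MT-ND4, TAR1-A and APOE, between 75.8-fold and 159-fold lower. The 8 highest by the same rule were Ighm (2.56-fold), Ca3 (2.36-fold), C3 (1.85-fold), Me1 (1.77-fold), Scd1 (1.71-fold), TBX5 (1.60-fold), Cib2 (1.55-fold) and Trdn (1.54-fold); the last 6 lie under 2-fold. Below that level, Bpifa1 had a log2 ratio of 3.49, Jchain 1.84, Cfd 1.73 and Ighg1 1.54. Each of these named ratios is of 1 assembled gene. Summed over all assembled genes of the name, the log2 ratio was -0.74 for C3, -0.14 for JCHAIN and 0.51 for ME1. These ratios come from 1 library against 1 library and have no replicate check.

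**Figure D2:**
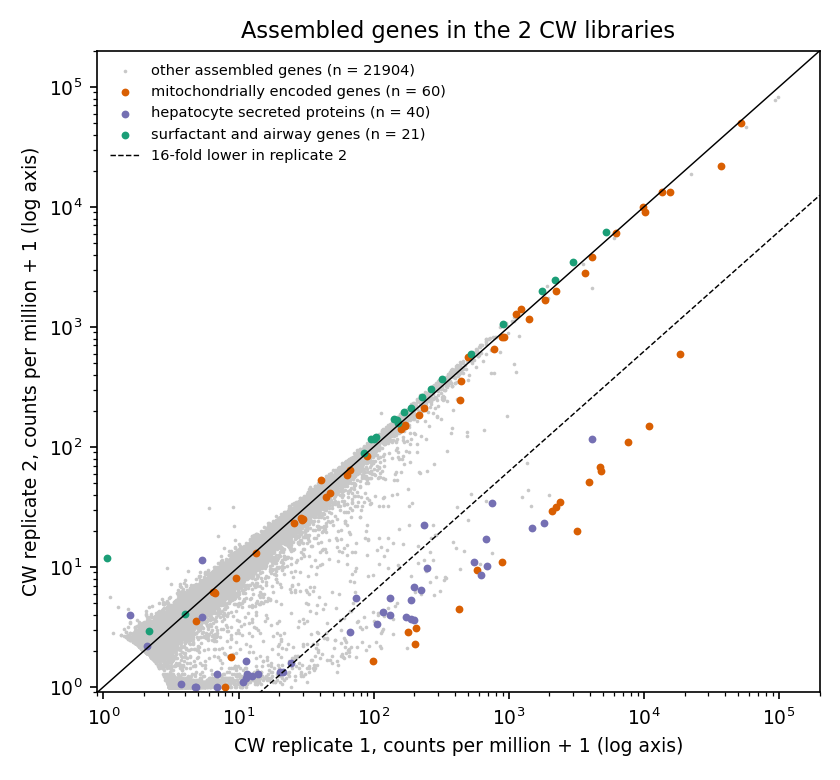
CPM + 1 of each tested assembled gene in CW replicate 1 (x, log axis) and replicate 2 (y, log axis), after TMM scaling; the solid line marks equality and the dashed line a 16-fold lower value in replicate 2. Most surfactant and airway genes (green) lie near equality, except BPIFA1 with 1 and 224 counts, while hepatocyte genes (purple) and part of the mitochondrial genes (orange) lie far below it.

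Mitochondrial genes split into separate sets of assembled genes. Of 60 assembled genes with a mitochondrial protein name and at least 100 summed counts, 41 lay within 2-fold between the libraries and 18 were over 16-fold lower in replicate 2. Of the 11 mitochondrial genes named, 9 had assembled genes of both kinds. For MT-ND3 those within 2-fold had best matches to mouse (674 and 1073 counts) and sheep (65 and 53 counts) only. MT-CO3, a core subunit of cytochrome c oxidase, had 1 assembled gene at 21210 and 24792 TPM and another at 15811 and 295 TPM. The 18 low assembled genes held 27.51% of mitochondrial counts in replicate 1 (Wilson 95% interval 27.47% to 27.56%) and 0.818% in replicate 2.

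**Figure D3:**
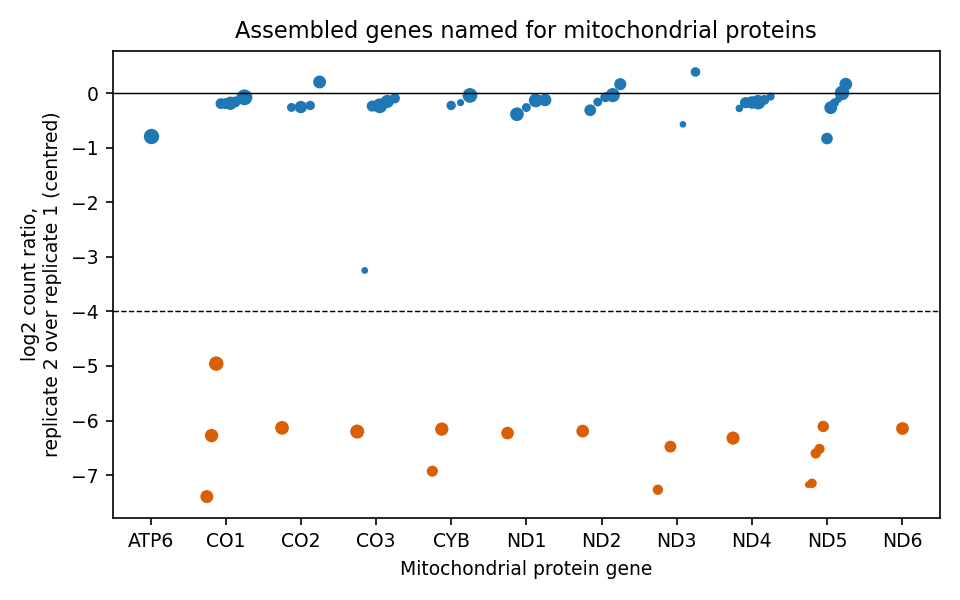
Centred log2 count ratio of replicate 2 over replicate 1 (y) for each assembled gene with a mitochondrial protein name (x), with point area growing with counts; orange points lie below the dashed line at a ratio of -4. The orange points have a median of -6.30 and the others a median of -0.17.

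Across 49649 genes, log2(TPM + 1) had a Pearson r of 0.676 and a Spearman rho of 0.566 between the libraries, with an SD of the log2 ratio of 1.16; genes are not independent replicates. Among genes within 2-fold and with 1000 to 3000 counts, the robust SD of the log2 ratio was 0.142 against 0.057 from counting alone, with a chi-square of 16.1 per degree of freedom. The libraries were counted as 2 samples because the labels give them as such; a spread above counting noise does not show that they came from separate animals.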

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

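The alternatives that leave out or redefine the 16-fold set, use the surfactant list, or keep the median with TMM scaling were chosen after the data were seen; the others were planned. The Pearson r moved from 0.676 to 0.466 with a pseudocount of 0.1, 0.707 without a filter, 0.66 at a mean of at least 10 TPM, and 0.703 without the 16-fold set; a change under 0.01 was counted as none, a tolerance chosen for this work, and the cause was not tested. Genes over 2-fold apart fell from 1521 to 430 at a mean of at least 10 CPM, where fewer genes are tested; the other settings gave 1099 to 2247, with 90.4% to 98.6% of them lower in replicate 2. The surfactant and airway share of TPM rose from a mean of 1.70% to 2.30% when the 10 highest genes were left out of the total, which that smaller total brings about. Without each replicate in turn, the shares ranged from 0.044% to 1.64% for hepatocyte secreted proteins and from 1.31% to 2.09% for surfactant and airway genes, and 22 to 25 lists had a median member at 10 TPM or more. The number of lists outside the percentile limits was 13 and stayed between 12 and 16 under its alternatives; without a filter on low values, metallothionein and zinc transport (-0.172), Kupffer cells and macrophages (-0.149), and pancreas and gut (-0.66) moved outside. Fatty acid and triglyceride synthesis went to 0.091 with library size scaling, which lifts most medians, so that lists between the limits such as metallothionein and zinc transport (0.114) also changed sign; its percentile was 0.49. Without the 16-fold set, iron and copper handling (-0.082) and the mitochondrial genome (-0.062) moved inside the limits, cytosolic ribosomal proteins (-0.063) moved outside, and 27 of 30 lists kept their side, lymphocytes changed sign, to 0.08, and 4 of the largest medians moved towards 0: to -1.10 for hepatocyte secreted proteins, -2.01 for urea cycle and amino acid breakdown, -1.50 for acute phase proteins and -0.64 for cytochrome P450 genes. The 16-fold set was chosen for low values in replicate 2, so the upward shifts without it follow from that choice. The replicate 1 share of counts in the 16-fold set was 9.646% at 8-fold, 6.744% at 32-fold and 8.985% on unscaled counts. No paired analysis was possible because there is 1 group. The planned results on the authors' comparison between caves were not run. With 1 library against 1, depth does not limit the large differences, but the spread between animals is unknown.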

Other observations

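All explanations and bounds in this part were set after the values were seen, including where a value came from a planned analysis, so each explanation here is a hypothesis found and tested on the same data.

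Further tissue marker lists, added after the data were seen, shared 0 symbols with the lists fixed before. Heart muscle genes summed to 467 ± 87.5 TPM (SD, n = 2), with TNNT2 at 95.02 ± 2.5 and MYL2 at 84.1 ± 20.4, and skeletal muscle genes to 335 ± 33.3, led by TNNT3 at 90.8 TPM. Kidney genes summed to 46.5 ± 11.9 TPM, skin genes to 39.5 ± 14.01, brain genes to 14.8 ± 3.0 and spleen B cell genes to 2.70 ± 1.2, and 0 testis genes were found. NKX2-1, a transcription factor of lung and thyroid, was at 58.0 ± 17.2 TPM, and FOXJ1, which drives motile cilia, at 69.3 ± 21.2.

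The first pattern is that hepatocyte transcripts and part of the mitochondrial assembled genes were far higher in replicate 1. The 424 assembled genes over 16-fold lower in replicate 2, by a TMM-scaled ratio of counts + 1 among genes with at least 100 summed counts, held 9.227% of counts in replicate 1 (Wilson 95% interval 9.214% to 9.24%) and 0.239% in replicate 2, against 1 gene over 16-fold higher by the same ratio, Bpifa1. Animal to animal differences in the expression of a single genome would move all assembled genes of a mitochondrial gene alike. Instead, 9 of 11 had both kinds, although for MT-ND3 the kind within 2-fold matched only mouse and sheep proteins. This covers the mitochondrial genes only. Animal to animal differences were not tested for the hepatocyte genes and stay open for them. Scaling is argued against by a hepatocyte list median of -4.72 under library size scaling. RNA from a second source mixed into replicate 1 at a single ratio may account for part of the set, but this could not be decided. Hepatocyte assembled genes and the 19 mitochondrial ones over 4-fold lower in replicate 2 had median ratios that differed by 0.92 on the log2 scale. That lies between the bounds of 0.5 and 1 that were set for and against such mixing. The quartiles were -5.85 to -4.90 for the hepatocyte and -6.77 to -6.15 for the mitochondrial assembled genes. Only the mitochondrial ones were chosen for low ratios. Among the hepatocyte ones, the same cut would drop only an APOA1 (-0.62) and an APOE (1.25) assembled gene, so that choice can account for little of the gap. The quartile ranges do not overlap, but the gap stays under the bound of 1 set against a single ratio. A single ratio was therefore neither shown nor excluded. The set also held 6 ribosomal protein names, each with another assembled gene within 2-fold, a count known before it was considered as evidence.

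The second pattern is that surfactant and airway transcripts lay far above hepatocyte transcripts in replicate 2, which is labelled liver. A small share of lung RNA in a liver library is argued against by the 0.044% of TPM in hepatocyte secreted proteins, although this low share is part of the pattern itself. Lowered expression of liver genes could not be decided. There were 20 surfactant and airway genes at 10 TPM or more, but their list was chosen from these libraries. In replicate 1, where hepatocyte genes were far higher, 18 reached that level too. That most RNA in replicate 2 came from a tissue other than liver, or that the library is mislabelled, stays open: the surfactant and airway sum was 39.6 times that of urea cycle and amino acid breakdown genes, which restates the pattern with another liver list and decides nothing. The same question is open for replicate 1. There, surfactant and airway genes took 1.31% of TPM and hepatocyte secreted proteins 1.64%. Of assembled genes with at least 100 summed counts, 94.42% lay within 2-fold between the libraries. In replicate 1 the surfactant sum was below the hepatocyte sum, but 1 short ALB assembled gene gave 6180 TPM of the latter, more than the gap. Of the surfactant sum, 1 Scgb3a1 assembled gene gave 8069 TPM. Lung as the source rests on a list chosen from these libraries, and heavy metal exposure cannot be assessed as a cause with 1 group.

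The third pattern is that, of 17 assembled genes with a protein match over 2-fold higher in replicate 2, 14 had a mouse protein as best match, against 12.7% of 13883 others, a tally of the genes in which it was noticed and not a test. They included Jchain, Ighg1 and Ighm of antibodies, the complement enzyme Cfd and the fatty acid synthase Fasn. For a mouse RNA trace raised by one factor in replicate 2, 8 mitochondrial assembled genes with mouse matches were examined. Their median log2 ratio was -0.18 (range -0.31 to 0.39). This argues against such a trace only if they are of mouse origin, which was not shown. A trace from particular mouse tissues may remain, as a best match does not show the species and the sequences were not used here; no biological explanation was tested.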
